A study of Hordeum vulgare with 4 samples.

How the data were processed

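Total RNA was extracted from inflorescence meristems at the double ridge stage of the barley cultivars GP and RD2715, with 2 samples per cultivar. Per the labels' protocols, a directional library kit was used and both ends of the fragments were sequenced on an Illumina HiSeq-X instrument. HISAT2, an aligner, and DESeq2, a package for testing counts, are named in the submitters' processing notes, with no version. How transcripts were assembled and quantified, the filters and the genome file are not given in the sources used here. The identifiers in the deposited table are those of the third Morex annotation release and of an assembly with the MSTRG prefix.

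The deposited table has 4 value columns, with one row per transcript. The values were inspected to see what the columns hold, including their totals and the correlations between columns. None of them entered a reported result, because no label of the samples contains the columns' names. The assignment of samples to cultivars was taken from the sample titles, and it could not be carried over to the columns. The depth per sample and the agreement of replicates are accordingly not reported.

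A comparison of RD2715 with GP on gene sums, tests of 34 gene lists, and a list of genes read in a single cultivar had been planned before the data were examined. These were not run, and 0 group comparisons were made. The rule for naming genes was also fixed then. It called for named genes with the strongest changes, for members of each list, chiefly called ones, and for genes read in a single cultivar. Some genes fixed by name were to be given whatever their result. The rule was not applied.

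The transcript identifiers alone were counted with Python 3.11.15. A Morex identifier was split into its gene, its chromosome and its transcript number, and an MSTRG identifier into its locus and its transcript number. Gene identifiers were searched in a RefSeq gene table of the Morex assembly, with 0 matches. No coordinates from that table were used.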

Results

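The series profiled RNA from barley (Hordeum vulgare) inflorescence meristems collected at the double ridge stage, when the shoot apex of a grass first shows paired leaf and spikelet ridges. The labels divide the 4 samples into 2 cultivars, GP and RD2715, with 2 replicates each. Nothing in the labels states that the replicates came from separate plants. The comparison implied by this design is RD2715 against GP, and the submitters placed it in the setting of early development and escape from heat late in the season.

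That comparison was not made here. The deposited table lists one value per transcript in 4 columns, and the names of these columns match no title, description or other label of the 4 samples. With these labels, a column could have been given a cultivar only from its place in the table or from its values. Values can show which columns are alike, but neither they nor the place names the cultivar of a library. No key from outside the labels was used. No level, fold change, depth or count of changed genes is therefore reported for either cultivar, and no statement is made about which genes were higher in RD2715 or in GP.

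Counting the listed transcripts did not require the columns to be matched to samples. Every row was counted whatever its values, so being listed does not show that a transcript was read in any sample. The table held 59911 different transcripts. Of these, 37962 carried identifiers of the third gene annotation release for the barley reference cultivar Morex, and 21949 carried identifiers beginning with MSTRG, the prefix that the assembler StringTie gives by default to loci of a merged assembly. The MSTRG transcripts were 36.6% of the list. They fell into 13139 loci. Counted per gene or locus, with MSTRG loci and Morex genes taken as separate, their share was 26.8%. A merged assembly can also give MSTRG identifiers to further transcripts of annotated genes, and this overlap was not tested, so some genes can be counted under both kinds of identifier. These shares describe the rows of the table and not the abundance of any RNA in the meristem.

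The Morex identifiers belonged to 35826 genes, of which 34089 had a single listed transcript and 1737 (4.85%) had at least 2. Several transcripts were more often listed for an MSTRG locus, where 4147 of the 13139 loci (31.6%) had at least 2. The gene with the most listed transcripts had 15, and the locus with the most had 64. Further transcripts of an annotated gene can be listed under an MSTRG identifier, and this overlap was not tested. The 4.85% and 31.6% therefore compare kinds of identifier, and not the number of transcripts made by annotated and other genes. These are complete counts of the list, so no sampling error or test applies to them.

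By the chromosome written in the Morex identifiers, chromosome 2H had the most listed transcripts, with 6158 transcripts of 5808 genes, or 16.5% of those assigned to a chromosome. Chromosome 4H had the fewest, with 4375 transcripts of 4088 genes (11.7%). The other chromosomes held between 4568 transcripts (6H) and 5882 transcripts (5H). A further 721 transcripts of 720 genes were on sequence not placed on a chromosome. The MSTRG identifiers carry no chromosome. The number of annotated genes per chromosome was not set beside these counts, and the values of the transcripts did not enter them. The ranking therefore describes the listed identifiers and not RNA in the meristem.

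None of the Morex identifiers was given a gene name here, and a single source of names was searched. The gene table used for names, made from the RefSeq annotation of the Morex assembly, held 0 of the 35826 gene identifiers. Flowering-time, MADS-box, homeobox, hormone and heat-response genes had been chosen as gene groups before the data were examined. They were not analysed here, because the comparison of the cultivars was not made and no gene was given a name. A search by protein motif, planned for some groups in case no descriptions existed, was not run.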

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

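None of the alternatives planned for the comparison of the cultivars was run, since the comparison itself was not made. No paired analysis was possible because the value columns carry neither a replicate number nor a cultivar that the labels give. The share of transcripts with an MSTRG identifier was recomputed in 2 ways chosen after seeing the data, and the other shares reported were not recomputed. It was 36.6% per transcript, 26.8% when counted per gene or locus, and 37.1% without the Morex transcripts on unplaced sequence. This last share could only rise, because Morex transcripts were left out and every MSTRG transcript was kept. The value per gene or locus counts MSTRG loci and Morex genes as separate, and their overlap was not tested. It is lower because the list held more transcripts per MSTRG locus (21949 in 13139 loci) than per Morex gene (37962 in 35826 genes).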
